A study of Mus musculus with 16 samples.

How the data were processed

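RNA of sorted HSC fractions was amplified, labelled with biotin and hybridised to Illumina mouse bead arrays, per the labels' protocols. The labels give 16 arrays in 4 groups, control (IFNgamma-deficient) and CD70TG (IFNgamma-deficient with the transgene) in the fractions labelled CD34- and CD34+, with 4 independent pools of 2 mice each. The values used are the authors' deposited log2-like values, 25697 probes by 16 arrays. Their range and the similar array medians (6.427 to 6.531) are those of log-transformed values already brought to a common scale. The base of the logarithm, the background correction and the normalization are not given in the sources used here, and a difference of 1 is a doubling only if the base is 2. A second table of 32 columns for 16 arrays, with signals and detection p-values, was not used, because its column names match no sample label. The planned background correction with limma's neqc and the planned filter on detection p-values needed that table. They were replaced, after the files were seen, by the deposited values as they stand and by a filter on dim probes. A probe was kept if its value exceeded the mode of the array's values by 1.64 SD of the background (estimated from values below the mode, density bandwidth 0.1) on at least 4 of the 16 arrays, which 15538 probes did.

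Gene names came from the platform annotation, updated through gene numbers: 23978 probes had 1 symbol, 0 several and 1719 none, and 23962 were matched by gene number. The kept probe with the highest mean over all arrays stood for a gene, and a probe without a symbol stood for itself, which gave 11839 tested features, 10896 of them named. Probes of 1 gene can disagree. Among the other probes of genes called between genotypes in CD34- cells, 898 of 1139 had the same direction and 26 were called the opposite way, and of the genes named by the rule below this concerned Car2, Gbp2, Srm and Birc2. No 2 arrays shared more than 0.288% identical values, so all 16 were kept as separate replicates.

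Differences between groups were tested with limma (version 3.58.1, R 4.3.3), using lmFit on 4 group means over all 16 arrays, which leaves 12 residual degrees of freedom, and eBayes with a trend, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. The 6 comparisons are CD70TG against control in each fraction and averaged over both, CD34+ against CD34- in each genotype, and the difference of the CD70TG effect between fractions. Before the data were examined, 26 gene lists were fixed (16 programmes and 10 sets of cell type markers), and 25 of them with at least 5 measured genes were tested with camera. The preset correlation between genes was 0.01, and each list was tested again with an estimated correlation. Of 13 lists called between genotypes in CD34- cells, 6 held with an estimated correlation, as did 7 of 12 in CD34+ cells, 8 of 13 on the average, 3 of 12 between the fractions of control mice, 2 of 16 between those of CD70TG mice and 2 of 3 for the interaction. The list of sex-linked transcripts, with 4 measured genes, was too short for this test (2 up and 0 down on the average). Its level was 8.15 ± 0.12 (SD) in control and 8.44 ± 0.07 in CD70TG CD34- arrays. In CD34+ arrays it was 8.33 ± 0.16 and 8.44 ± 0.06. Whether the sex of the pooled mice differed between the genotypes was not tested. Named genes were chosen by a rule fixed before the data were examined: in each comparison the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups (no such condition for the interaction), up to 4 called members of each list with the smallest p, and 11 genes of the sort gate and the transgenic design. The text names part of them. Groups without overlap occurred for 23.1% and 21.5% of all tested genes between genotypes in CD34- and CD34+ cells and for 12.1% and 12.2% between fractions in control and CD70TG mice, where chance gives 2.86% for 4 against 4 arrays.

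The fit and the list tests were tested on simulated arrays with the means and spread of these 11839 genes, each gene drawn independently. In the real arrays the first component held 35.0% of the within-group variance, and the simulation does not hold such shared variation. In the comparison of genotypes in CD34- cells, 59% of 100 genes changed by 0.5 log2 and 99% of 100 changed by 1 log2 were recovered, and for the interaction 34% and 83%. Other choices fixed before the data were examined were no filter on dim probes, each probe on its own, only the arrays compared, the replicate number as a fixed and as a random block, array weights, a minimum fold of 1.2 and leaving out each array. A stricter filter was planned on detection p-values and run, after the files were seen, as values 3 SD above background on all 4 arrays of a group. Also added after seeing the data were quantile normalization, equal array medians, leaving out both arrays that stood apart, and the probe discordance index as a covariate. The index is the first principal component, over arrays, of the differences between the 2 probes of 747 genes with exactly 2 probes of mean 8 or more. A first form of the index, from 1328 genes with 2 probes above background by 3 SD on at least 12 arrays, was tried before this one, its calls were seen, and it is reported beside it (correlation of both forms across arrays 0.999). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.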

Results

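Gene expression was measured on 16 mouse bead arrays, from hematopoietic stem cell (HSC) fractions sorted from C57Bl/6 mice. The design crossed 2 genotypes with 2 fractions, and each array held RNA pooled from 2 mice, with 4 independent pools in each of the 4 groups. CD70TG mice carried a CD70 transgene; CD70 is the ligand of CD27, a receptor of the TNF receptor family found on lymphocytes and hematopoietic progenitors. Transgenic and control mice both lacked IFNgamma, so the genotype comparison concerns the transgene on a background without that cytokine. The fractions are labelled CD34- (long-term HSC) and CD34+ (short-term HSC) and were sorted within lineage-negative, c-Kit+ and Sca-1+ cells. The sort protocol in the labels lists the same CD34-Flt3- gate for both fractions, against the stated design, and the fractions are therefore named by their labels here. Deposited values lay on a log2-like scale with array medians of 6.427 to 6.531. Of the probes of an array, 50.1% to 57.5% lay above its background. Replicate arrays correlated across probes at r = 0.986 to 0.996. All differences below are in units of the deposited log2 values, given ± SE of the limma fit with n = 4 arrays per group, and they understate changes of genes near background, where values are compressed. The p-values measure the spread between independent pools of mice, and the number of arrays limits their precision, with a median SE of 0.115 for a difference between 2 groups.

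Genes of the sort gate and of the transgenic design were examined first. Cd34, the antigen that names the fractions, differed by -0.17 ± 0.12 between CD34+ and CD34- arrays of control mice, with a 95% interval from -0.44 to 0.09. In CD70TG mice the difference was -0.09 ± 0.12, with an interval from -0.36 to 0.17, so a larger Cd34 transcript level in the fraction labelled CD34+ was not detected in either genotype. Cd48 was higher in CD34+ arrays of control mice (1.02, 95% interval 0.46 to 1.59, adjusted p = 0.0235). It did not pass in CD70TG mice (0.55, adjusted p = 0.332). In control mice Flt3 (0.25, adjusted p = 0.766), Slamf1 (0.09, 0.68), Fcgr3 (-0.055, 0.761) and Il7r (-0.74, 0.0796) did not pass. In CD70TG mice Fcgr3 was lower (-0.59, adjusted p = 0.000178). Ifng, absent from both genotypes by design, lay near background in every group, at group means of 6.31 to 6.39, and checks no label. Cd70 lay at background in both CD34- groups (6.14 ± 0.07 in control and 6.00 ± 0.13 in CD70TG, mean ± SD) and was highest in control CD34+ arrays (8.29 ± 1.05), above CD70TG CD34+ arrays (6.80 ± 0.10). Whether its probe reads the transgene is not given in the sources used here. Cd27, the receptor of CD70, was lower in CD70TG arrays averaged over both fractions (-0.33 ± 0.09, adjusted p = 0.00777), but not with the probe discordance index, described below, as a covariate (-0.08, adjusted p = 0.819), nor against a minimum fold of 1.2. Kit and Ly6a (Sca-1) had no tested probe under these symbols and were not analysed here.

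Over all 11839 genes and unnamed probes tested, the first principal component held 50.6% of the variance, and the second, with 17.4%, separated the fractions. On the first component control arrays lay below CD70TG arrays except that control CD34+ replicate 4 (5.48) lay above CD70TG CD34- replicate 2 (0.670). Across 747 genes with exactly 2 bright probes, the difference between the probes of a gene also varied from array to array along 1 main axis, which held 58.7% of the variance of those differences. The position of an array on this axis, here called the probe discordance index and scaled to an SD of 1, averaged -1.17 ± 0.451 (SD) in control CD34- arrays and 0.691 ± 0.680 in CD70TG CD34- arrays. The CD34+ groups averaged -0.362 ± 0.792 in control and 0.839 ± 0.371 in CD70TG. The genotype difference was 1.86 in CD34- arrays (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 arrays can give; adjusted p = 0.114 over 4 comparisons) and 1.201 in CD34+ arrays (exact permutation p = 0.0571, adjusted p = 0.114). Within groups, the index followed the first component of all genes (Pearson r = 0.986, Spearman rho = 0.985, permutation p = 1e-05 for both, the smallest that the permutations can give), and r was 0.977 without the 2 arrays farthest from the median. The brighter probe of each of the 747 genes also stood for its gene in that component. The 2 axes thus share measured values, and the permutation test does not allow for this. Because the index followed that component, genotype differences are also given with the index as a covariate, a fit chosen after the data were seen.

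**Figure D1:**
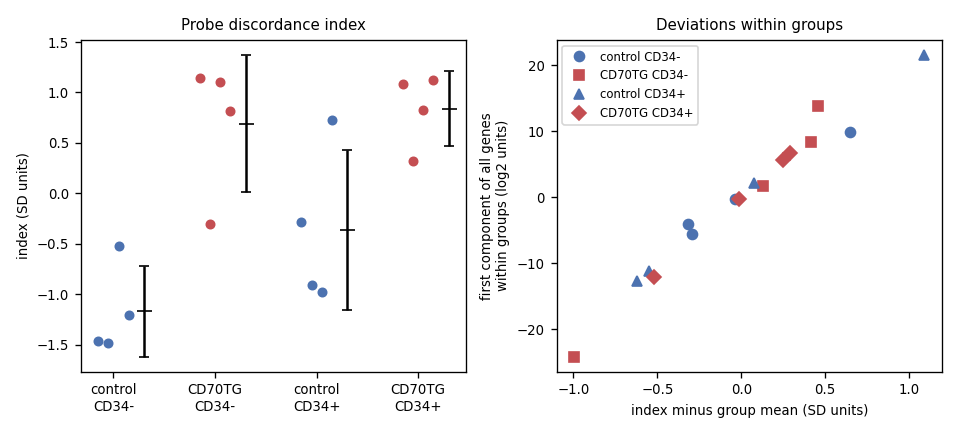
The left panel shows the probe discordance index (SD units) of each of the 16 arrays by group, with the group mean and SD in black, and CD70TG arrays average 0.691 and 0.839 against -1.17 and -0.362 in control arrays. The right panel sets each array's index minus its group mean against the first component of all genes within groups (log2 units), which rise together at r = 0.986.

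In the fraction labelled CD34-, CD70TG cells showed lower HSC genes and higher cell cycle and granule genes than control cells (n = 4 arrays per group). Ctsg, the granule protease cathepsin G, rose by 3.85 ± 0.25, adjusted p = 1.12e-08, from 8.72 ± 0.54 to 12.57 ± 0.37 (mean ± SD). Vwf, a platelet adhesion protein also made by HSC, went the other way (-1.70 ± 0.14, adjusted p = 8.36e-08), from 9.75 ± 0.16 to 8.05 ± 0.29. In all, 1891 genes were higher and 1396 lower in CD70TG arrays at an adjusted p under 0.05, of which 384 and 111 differed by 1 log2 unit or more. After quantile normalization the split was 1618 higher and 2000 lower, so the number of genes on each side depends on the scaling of the arrays.

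Of 33 measured long-term HSC genes, 21 fell, 0 rose and 12 did not pass (1 up and 22 down adjusted over the list alone; median -0.49; camera adjusted p = 1.09e-11, adjusted p = 0.000519 with an estimated correlation). Those that fell included Sult1a1, a sulfotransferase (-2.20 ± 0.17), Tgm2, a transglutaminase (-1.95 ± 0.13), and Hoxb5, a homeobox factor restricted to HSC (-1.41 ± 0.11), each at an adjusted p of 5.82e-08 or less. Slamf1, which encodes CD150, fell by 0.66 ± 0.12, adjusted p = 0.000398. The other large falls were in Upp1, a uridine phosphorylase (-2.18 ± 0.18), Wfdc2 (-2.03 ± 0.16) and Unc45b, a myosin chaperone (-1.82 ± 0.15). Snrpn, an imprinted splicing factor gene, fell too (-1.67 ± 0.15), as did Hgfac (-1.59 ± 0.13), Cdkn1c, the cell cycle inhibitor p57 (-1.55 ± 0.13), and Cish, a feedback inhibitor of cytokine signalling (-1.54 ± 0.17, adjusted p = 3.02e-06, the largest p of these). With the index as a covariate Cish was at -0.89, adjusted p = 0.00626, and with the first form of the index Upp1 was at -1.445, adjusted p = 0.000127.

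All but 1 of the 22 measured G2 and M phase genes rose (21 up, 0 down; 22 up adjusted over the list alone; median 1.28; camera adjusted p = 7.66e-22, adjusted p = 0.00199 with an estimated correlation). Examples are the spindle genes Kif2c (1.93 ± 0.11), Nusap1 (1.95 ± 0.14) and Tpx2 (1.71 ± 0.13) and the checkpoint kinase gene Ttk (1.58 ± 0.13, adjusted p = 1.37e-07). Among 28 S phase genes, 19 rose and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 9.72e-11, adjusted p = 0.00286 with an estimated correlation). They include Rrm1, a ribonucleotide reductase subunit (0.98 ± 0.10), Clspn (1.08 ± 0.11) and the replication initiation factor Mcm10 (1.10 ± 0.13, adjusted p = 5.02e-06). Shcbp1, which is active in dividing cells, rose by 2.42 ± 0.25, adjusted p = 1.17e-06. With the index as a covariate Shcbp1 was at 1.25, adjusted p = 0.000275, and Ttk at 0.98, adjusted p = 5.06e-05. Myeloid progenitor and granule genes rose at 22 of 26 members with 0 down (23 up adjusted over the list alone; camera adjusted p = 3.96e-13, adjusted p = 0.0268 with an estimated correlation). They include Ctsg, the progenitor marker Ms4a3 (2.62 ± 0.16), neutrophil elastase Elane (2.44 ± 0.26) and myeloperoxidase Mpo (2.30 ± 0.14). Of 14 mast cell, basophil and eosinophil markers, 6 rose and 0 fell (6 up adjusted over the list alone; camera adjusted p = 0.000833, adjusted p = 0.0479 with an estimated correlation). Examples are the basophil protease Mcpt8 at 2.63 ± 0.16, the histamine enzyme Hdc at 1.87 ± 0.23 and the mast cell carboxypeptidase Cpa3 at 1.56 ± 0.14, adjusted p = 3.33e-07.

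Monocyte and macrophage markers were higher in CD70TG CD34- arrays at 15 of 18 members and lower at 0 (16 up adjusted over the list alone; median 0.98; camera adjusted p = 3.96e-13, adjusted p = 0.00199 with an estimated correlation). They included the mannose receptor Mrc1 (1.85 ± 0.12), the complement component C1qc (1.05 ± 0.08), the adhesion receptor Adgre1 (1.77 ± 0.13), and the iron exporter Slc40a1 (1.77 ± 0.15, adjusted p = 1.06e-07), while the adhesion molecule Vcam1 rose by 2.73 ± 0.24. These markers of another cell type were measured in cells sorted as lineage-negative, c-Kit+ and Sca-1+. Neutrophil granule markers rose at 10 of 18 members (13 adjusted over the list alone; camera adjusted p = 0.000114, adjusted p = 0.381 with an estimated correlation). They include S100a8 (0.90 ± 0.18) and the antimicrobial peptide Camp (0.90 ± 0.21, adjusted p = 0.0039). Oxidative phosphorylation genes rose at 16 of 36 and fell at 1 (18 and 1 adjusted over the list alone; camera adjusted p = 0.000232, adjusted p = 0.0553 with an estimated correlation). An example is the complex I subunit Ndufb6 at 0.75 ± 0.10. With the index as a covariate Ndufb6 was at 0.49, adjusted p = 0.0407, and Camp at 1.61, adjusted p = 0.000412, and with the first form of the index Ndufb6 did not pass (adjusted p = 0.059). The mean difference of neutrophil granule markers went from 0.59 to 1.004 with the index, and its p with an estimated correlation, without adjustment, from 0.198 to 0.0419 (camera test). Ribosome biogenesis and Myc target genes rose at 10 of 27 and fell at 1 (13 and 1 adjusted over the list alone; camera adjusted p = 0.00884, adjusted p = 0.136 with an estimated correlation).

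B cell and plasma cell markers fell at 9 of 13 members (9 adjusted over the list alone; camera adjusted p = 0.000928, adjusted p = 0.153 with an estimated correlation). They include Mzb1 (-0.85 ± 0.20) and the B cell receptor chain Cd79b (-0.49 ± 0.12, adjusted p = 0.00606). NF-kB and TNF receptor target genes fell at 8 of 28 and rose at 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00805, adjusted p = 0.136 with an estimated correlation). Examples are the adaptor Traf1 at -0.93 ± 0.08 and lymphotoxin beta, Ltb, at -0.82 ± 0.11, adjusted p = 3.14e-05. Type I interferon induced genes fell at 8 of 30 and rose at 4 (8 and 4 adjusted over the list alone; camera adjusted p = 0.0353, adjusted p = 0.153 with an estimated correlation). The list passed narrowly, with an adjusted p of 0.0685 without control CD34- replicate 3 and 0.0764 without CD70TG CD34- replicate 4. Interferon gamma induced and antigen presentation genes fell at 7 of 29 and rose at 3 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0364, adjusted p = 0.278 with an estimated correlation). That call was lost without control CD34- replicate 1 or 4 or CD70TG CD34- replicate 2 or 3, at adjusted p from 0.056 to 0.0856.

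Flt3 and Cd48, surface receptors of multipotent progenitors, were also higher in CD70TG CD34- arrays (1.94 ± 0.41 and 1.68 ± 0.27). So were the nuclear RNA-binding protein gene Nono (3.14 ± 0.57), the chaperone genes Hsp90aa1 (2.92 ± 0.48) and Hspa5 (2.40 ± 0.43) and Nudt3 (2.72 ± 0.59, adjusted p = 0.002, the largest p of the 6). With the probe discordance index as a covariate none of the 6 passed. Flt3 was then at 0.02, adjusted p = 0.987, and Cd48 at 0.43, adjusted p = 0.319. Nono was at 0.16, adjusted p = 0.806, and Hsp90aa1 at 0.44, adjusted p = 0.304. The other genes were Hspa5 at 0.42, adjusted p = 0.587 and Nudt3 at -0.35, adjusted p = 0.527. Calls of the respiratory chain genes Uqcrb (1.53 ± 0.25), Ndufa4 (0.84 ± 0.12) and Atp5a1 (1.38 ± 0.23) ended in the same way, at 0.42, adjusted p = 0.345, at 0.58, adjusted p = 0.058 and at 0.26, adjusted p = 0.405. Mzb1 and Cd79b, the latter also lost against a minimum fold of 1.2 (adjusted p = 0.264), were then at -0.31, adjusted p = 0.621 and -0.05, adjusted p = 0.913, and the B cell list lost its call (camera adjusted p = 0.131). With the index, 760 genes were called (466 higher, 294 lower), of which 656 were among the 3287 called without it, and the HSC, G2 and M phase, S phase, granule and macrophage lists kept their calls. Cd27 (-0.34 ± 0.13, adjusted p = 0.0517) missed the threshold with all arrays, and passed at adjusted p from 0.0145 to 0.0484 without control CD34- replicate 2, CD70TG CD34- replicate 2 or 4, or control CD34+ replicate 4. With all arrays it passed with the replicate number as a random effect (adjusted p = 0.049), array weights (0.00682), the stricter filter (0.0441) and quantile normalization (0.00752). It did not pass with the index as a covariate, where Cd27 averaged over both fractions was at -0.08, adjusted p = 0.819. Cd34 (-0.10 ± 0.12, adjusted p = 0.59) and Cd70 (-0.14 ± 0.31, adjusted p = 0.777) did not pass.

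**Figure D2:**
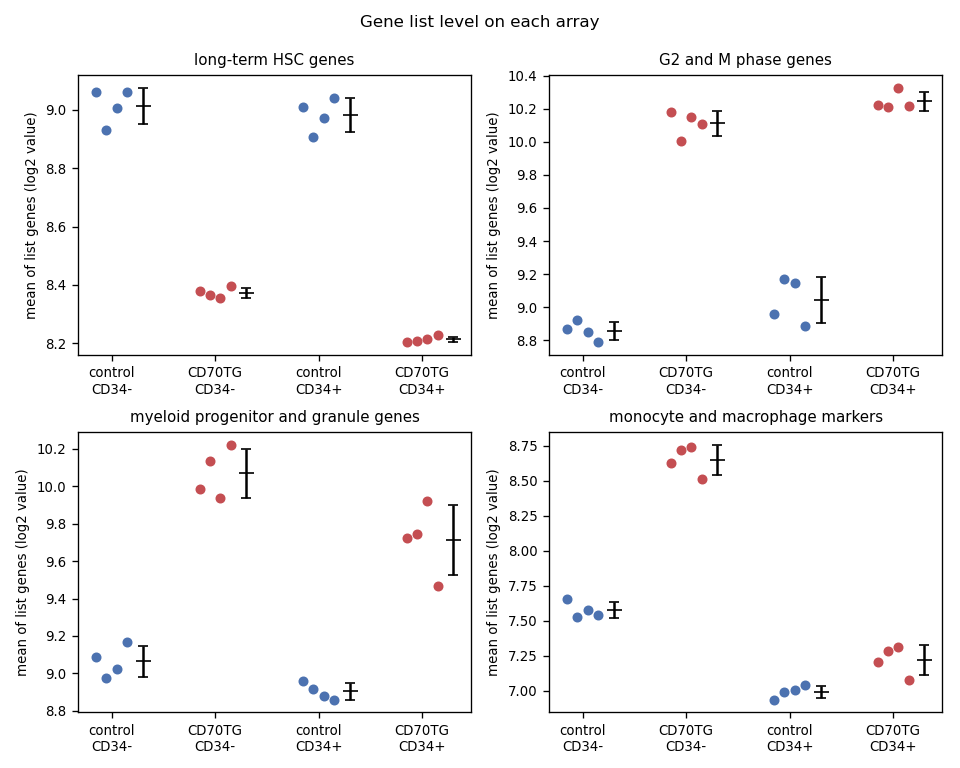
Each point is the mean deposited log2 value over the measured genes of a list on 1 array, for the 4 arrays of each group, with the group mean and SD in black. Long-term HSC genes lie lower on all CD70TG arrays, by mean differences of -0.64 and -0.77 in the fractions labelled CD34- and CD34+. G2 and M phase and granule genes lie higher, while macrophage markers are highest in CD70TG CD34- arrays.

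In the fraction labelled CD34+, CD70TG arrays again had lower HSC genes and higher cell cycle and granule genes than control arrays (n = 4 arrays per group). The largest rises were in granule and myeloid genes, with Ctsg at 3.38 ± 0.25, Mcpt8 at 2.34 ± 0.16, Mpo at 2.05 ± 0.14, and Elane at 1.92 ± 0.26. Also among the largest rises were the coagulation factor subunit F13a1 at 2.03 ± 0.21, the myeloid transcription factor Irf8 at 1.97 ± 0.23 and Anxa3 at 1.92 ± 0.19. The largest falls were in Sult1a1 (-2.55 ± 0.17), Unc45b (-2.28 ± 0.15), Tgm2 (-2.10 ± 0.13), Wfdc2 (-2.08 ± 0.16) and Vwf (-1.86 ± 0.14). Falls were also large in Bdh2 (-1.83 ± 0.12), Grb10, an imprinted adaptor of growth factor receptors (-1.83 ± 0.12), Upp1 (-1.79 ± 0.18), Art4 (-1.74 ± 0.14) and Snrpn (-1.71 ± 0.15). Among all these genes the largest adjusted p was 3.31e-05, for Elane. In all, 898 genes were higher and 1255 lower, of which 136 and 121 differed by 1 log2 unit or more. With the probe discordance index as a covariate 1113 genes were called (455 higher, 658 lower), 921 of them shared with the fit without it.

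Long-term HSC genes fell at 22 of 33 members and rose at 0 (23 down adjusted over the list alone; median -0.61; camera adjusted p = 3.84e-17, adjusted p = 6.24e-05 with an estimated correlation), and Slamf1 was at -0.78 ± 0.12, adjusted p = 0.000104. All 22 measured G2 and M phase genes rose (22 adjusted over the list alone; median 1.17; camera adjusted p = 1.75e-28, adjusted p = 0.000817 with an estimated correlation). They include Kif2c (1.83 ± 0.11) and the mitotic kinase genes Plk1 (1.86 ± 0.16) and Aurka (1.59 ± 0.13, adjusted p = 1.31e-07). Shcbp1 rose by 1.85 ± 0.25, and was at 1.09, adjusted p = 6.48e-05, with the index. S phase genes rose at 17 of 28 and fell at 1 (24 and 1 adjusted over the list alone; camera adjusted p = 1.17e-12, adjusted p = 0.00169 with an estimated correlation). An example is the ribonucleotide reductase subunit Rrm2 at 1.87 ± 0.25, adjusted p = 2.84e-05. Myeloid progenitor and granule genes rose at 18 of 26 with 0 down (19 up and 1 down adjusted over the list alone; camera adjusted p = 7.89e-12, adjusted p = 0.0334 with an estimated correlation). Mast cell, basophil and eosinophil markers rose at 8 of 14 and fell at 1 (11 and 1 adjusted over the list alone; camera adjusted p = 1.28e-05, adjusted p = 0.0146 with an estimated correlation). Examples are Hdc at 1.73 ± 0.23 and the tryptase Tpsb2 at 1.30 ± 0.19, adjusted p = 8.75e-05. Oxidative phosphorylation genes rose at 10 of 36 (13 adjusted over the list alone; camera adjusted p = 0.000144, adjusted p = 0.0498 with an estimated correlation). Ribosome biogenesis and Myc target genes rose at 9 of 27 (10 adjusted over the list alone; camera adjusted p = 0.00132, adjusted p = 0.0623 with an estimated correlation). Neutrophil granule markers rose at 5 of 18 (7 adjusted over the list alone; camera adjusted p = 0.000321, adjusted p = 0.39 with an estimated correlation).

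Type I interferon induced genes fell at 8 of 30 members with 0 up (10 down adjusted over the list alone; camera adjusted p = 8.48e-05, adjusted p = 0.0196 with an estimated correlation). They include Samd9l (-0.74 ± 0.09) and the antiviral genes Mx2 (-0.66 ± 0.12), Oas2 (-0.90 ± 0.20) and Rsad2 (-0.92 ± 0.21, adjusted p = 0.00424). Oas2 and Rsad2 lost their calls with the index as a covariate, at -0.59, adjusted p = 0.107 and -0.53, adjusted p = 0.159, and Rsad2 also against a minimum fold of 1.2 (adjusted p = 0.0558). Interferon gamma induced and antigen presentation genes fell at 6 of 29 (6 adjusted over the list alone; camera adjusted p = 0.0214, adjusted p = 0.236 with an estimated correlation), a call lost without control CD34+ replicate 1 (adjusted p = 0.0596). Megakaryocyte and platelet markers fell at 8 of 15 (8 adjusted over the list alone; camera adjusted p = 5.99e-05, adjusted p = 0.112 with an estimated correlation). They include the platelet glycoprotein genes Gp9 (-0.79 ± 0.11), Gp1bb (-0.72 ± 0.11) and Gp5 (-0.87 ± 0.15) and the platelet receptor Treml1 (-0.99 ± 0.17, adjusted p = 0.00044). B cell and plasma cell markers fell at 5 of 13 (5 adjusted over the list alone; camera adjusted p = 0.00134, adjusted p = 0.192 with an estimated correlation). Their mean difference went from -0.43 to -0.23 with the index (adjusted p = 0.0486), and with its first form the call was lost (adjusted p = 0.0526). That of neutrophil granule markers went from 0.44 to 0.71 with the index, with an unadjusted camera p of 0.234 before and 0.069 after by the estimated correlation. Monocyte and macrophage markers, 5 up and 2 down of 18 (5 and 2 adjusted over the list alone), did not pass as a list (camera adjusted p = 0.0961, adjusted p = 0.379 with an estimated correlation). Cd48 rose by 1.21 ± 0.27, adjusted p = 0.00391, and was at 0.40, adjusted p = 0.196 with the index. Cd70 was lower in CD70TG than in control CD34+ arrays (-1.50 ± 0.31, adjusted p = 0.0022), a call that ended with the index (-0.95, adjusted p = 0.0823). Flt3 (1.08 ± 0.41, adjusted p = 0.073) passed without CD70TG CD34- replicate 2, CD70TG CD34+ replicate 2 or control CD34+ replicate 4 (adjusted p from 0.00603 to 0.0301). It also passed with array weights (0.0112), the replicate number as a fixed block (0.018) or only the arrays compared (0.0169), but was at -0.16, adjusted p = 0.796, with the index. Cd27 (-0.31 ± 0.13, adjusted p = 0.103) passed without control CD34+ replicate 4 (-0.44, adjusted p = 0.00838) and with array weights (0.0168), but not with the index as a covariate. Cd34 was at -0.02 ± 0.12, adjusted p = 0.923, and turned positive, up to 0.06, without control CD34+ replicate 1 or 3 or CD70TG CD34+ replicate 1.

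The genotype differences of the 2 fractions, which share no arrays, correlated at r = 0.857 across genes, which are not independent replicates. The labels do not say whether both fractions were sorted from the same mice. If they were, the 2 differences would not be independent of each other. Of the called genes, 752 were higher and 853 lower in CD70TG arrays of both fractions, where independent lists would share 143 and 148, and 6 were called in opposite directions. The probe discordance index was higher on average in CD70TG arrays of both fractions, by 1.86 in CD34- and 1.201 in CD34+ arrays. In CD34- arrays the genotypes did not overlap, with a highest control value of -0.519 and a lowest CD70TG value of -0.304. The exact permutation test did not pass (adjusted p = 0.114 in each), but 4 against 4 arrays give at least 0.0286 before adjustment. Not passing therefore says little. The loading of genes on the first component within groups correlated with the genotype difference at r = 0.612 in CD34- and 0.501 in CD34+ cells. Averaged over both fractions, 2380 genes were higher and 2228 lower. The balance turned with quantile normalization (2094 higher, 2668 lower), with equal array medians (2046 and 2403) and without control CD34- replicate 2 (2243 and 2321). With the index 1185 (603 higher, 582 lower) were called, 1041 of them shared. Ctsg (3.61 ± 0.18), Mcpt8 (2.49 ± 0.11), the spindle gene Aspm (1.90 ± 0.12) and the DNA glycosylase Neil3 (1.86 ± 0.18, adjusted p = 1.92e-07) were among the largest rises, and Neil3 was at 0.85, adjusted p = 0.000157, with the index. Vwf (-1.78 ± 0.10), Pdzk1ip1 (-1.59 ± 0.11) and the imprinted gene Ndn (-1.54 ± 0.09, adjusted p = 6.48e-10) were among the largest falls. On this average, long-term HSC genes were 2 up and 22 down (camera adjusted p = 5.67e-13, adjusted p = 0.000269 with an estimated correlation). Type I interferon induced genes were 3 up and 14 down (camera adjusted p = 0.00148, adjusted p = 0.0421 with an estimated correlation), and oxidative phosphorylation genes were 20 up and 1 down (camera adjusted p = 8.22e-05, adjusted p = 0.042 with an estimated correlation). Lists that did not pass on the average were those of multipotent progenitor and early lymphoid genes (3 up, 6 down, adjusted p = 0.498), Wnt (4 and 3, 0.703), Notch (2 and 1, 0.993) and p53 targets (6 and 2, 0.528), and immediate early and heat shock genes (2 and 6, 0.34). The same held for glycolysis and hypoxia genes (4 and 8, 0.124) and cytosolic ribosomal protein genes (8 and 11, 0.434). Markers of other cell types that did not pass as lists were those of megakaryocytes and platelets (1 and 7, 0.0795), T and NK cells (1 and 4, 0.48), erythroid cells (2 and 7, 0.275), dendritic cells (4 and 3, 0.703) and endothelial and stromal cells (4 and 3, 0.993).

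**Figure D3:**
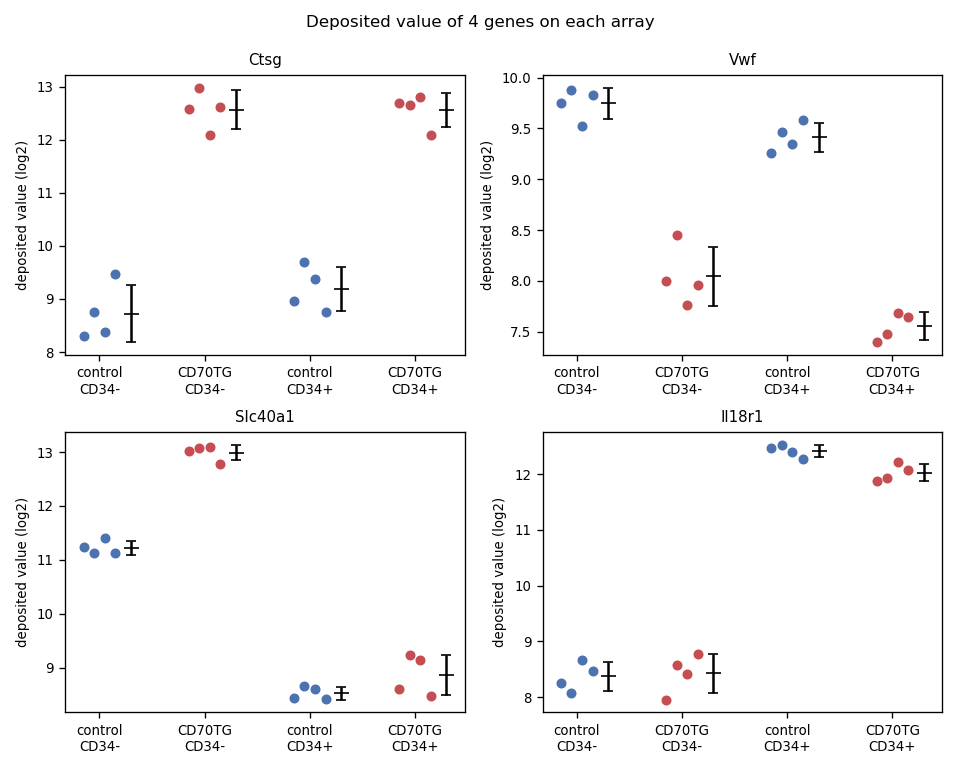
Deposited log2 values of Ctsg, Vwf, Slc40a1 and Il18r1 on each of the 4 arrays of a group, with the group mean and SD in black. Ctsg is higher and Vwf lower in CD70TG arrays of both fractions (3.85 ± 0.25 and -1.70 ± 0.14 in CD34- cells), Slc40a1 is lower in CD34+ than in CD34- arrays, and Il18r1 is higher.

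Between the fractions of control mice, arrays labelled CD34+ had more transcript of the interleukin 18 receptor gene Il18r1 (4.04 ± 0.16), the platelet chemokine Pf4 (2.74 ± 0.17), the chemokine-binding receptor Ackr1 (2.71 ± 0.11) and Cpa3 (2.29 ± 0.14) than arrays labelled CD34- (n = 4 arrays per group). Also among the largest rises were Erdr1 (3.54 ± 0.52), Lypd6b (2.60 ± 0.16), the adaptor Lpxn (2.55 ± 0.15), the membrane trafficking gene Ehd3 (2.36 ± 0.11), Cd70 (2.15 ± 0.31) and the lymphocyte receptor Cd96 (2.14 ± 0.16), all at an adjusted p of 0.000184 or less. The largest falls were in Slc40a1 (-2.69 ± 0.15), Emp1 (-2.51 ± 0.25), the chemokines Ccl3 (-2.04 ± 0.17) and Ccl4 (-2.01 ± 0.15) and Wfdc18 (-1.99 ± 0.15). Next came the sphingosine kinase Sphk1 (-1.81 ± 0.30), the amino acid transporter Slc38a5 (-1.78 ± 0.34), the lectin Fcna (-1.72 ± 0.10) and the formyl peptide receptor Fpr2 (-1.71 ± 0.31), all at an adjusted p of 0.00228 or less. Fos fell by 1.83 ± 0.53, adjusted p = 0.0411. Its call was lost without any 1 of control CD34- replicates 1, 2 and 4, control CD34+ replicates 1 and 4, CD70TG CD34- replicate 4 or CD70TG CD34+ replicate 1 (-1.87 to -1.22, adjusted p from 0.0506 to 0.129). It was lost as well with the index (-0.98, adjusted p = 0.195), with array weights (0.0911), with only the arrays compared (0.0656) and against a minimum fold of 1.2 (0.194). In all, 472 genes were higher and 512 lower in CD34+ arrays, a balance that turned with equal array medians (520 and 398) and without control CD34- replicate 3 (669 and 503) or control CD34+ replicate 3 (422 and 412). The count fell from 984 to 622 without control CD34- replicate 4, to 637 without control CD34+ replicate 4, and to 482 in a fit of the control arrays alone.

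Megakaryocyte and platelet markers rose at 8 of 15 members and fell at 1 (10 and 1 adjusted over the list alone; camera adjusted p = 5.77e-10, adjusted p = 0.0373 with an estimated correlation), with Pf4, the integrin Itga2b (1.52 ± 0.15), Gp1bb (0.88 ± 0.11) and the thrombin receptor F2r (0.73 ± 0.09, adjusted p = 2.77e-05). Monocyte and macrophage markers were lower in CD34+ arrays at 9 of 18 and higher at 1 (12 and 3 adjusted over the list alone; camera adjusted p = 4.06e-07, adjusted p = 0.036 with an estimated correlation). Examples are C1qb (-1.67 ± 0.14), the receptor kinase Axl (-1.40 ± 0.18) and Mrc1 (-1.003 ± 0.124, adjusted p = 2.77e-05). Type I interferon induced genes fell at 10 of 30 and rose at 1 (12 and 1 adjusted over the list alone; camera adjusted p = 4.9e-05, adjusted p = 0.036 with an estimated correlation). Examples are Usp18 (-0.998 ± 0.122), Mx2 (-1.002 ± 0.123) and Ifit3 (-0.98 ± 0.12, adjusted p = 3.57e-05). Neutrophil granule markers fell at 12 of 18 with 0 up (12 down adjusted over the list alone; camera adjusted p = 9.59e-12, adjusted p = 0.188 with an estimated correlation). They include S100a8 (-1.39 ± 0.18), Ngp (-1.35 ± 0.22) and Chil3 (-1.25 ± 0.22, adjusted p = 0.00132). NF-kB and TNF receptor target genes went both ways, 9 up and 2 down of 28 (10 and 3 adjusted over the list alone; camera adjusted p = 0.0272, adjusted p = 0.221 with an estimated correlation; 0.063 with the preset correlation without control CD34- replicate 3). The NF-kB subunit Nfkb2 (1.43 ± 0.13) and Ltb (1.60 ± 0.11) rose, while Ccl3 and Ccl4, chemokines of activated leukocytes, are the 2 that fell. Immediate early and heat shock genes fell at 8 of 24 (12 down and 2 up adjusted over the list alone; camera adjusted p = 0.000826, adjusted p = 0.221 with an estimated correlation). An example is Egr1 at -1.44 ± 0.24, adjusted p = 0.000784. The mean difference of this list went from -0.44 to -0.29 with the first form of the index (camera adjusted p = 0.00731). Long-term HSC genes were 2 up and 3 down and did not pass as a list (median -0.05; camera adjusted p = 0.768).

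Lists that passed in this comparison with the preset correlation alone were multipotent progenitor and early lymphoid genes (1 up, 6 down; camera adjusted p = 0.00597, adjusted p = 0.221 with an estimated correlation; 0.0515 with the first form of the index) and oxidative phosphorylation genes (4 up, 0 down; camera adjusted p = 0.00603, adjusted p = 0.214 with an estimated correlation). G2 and M phase genes passed in the same way (4 up, 0 down; camera adjusted p = 0.00586, adjusted p = 0.24 with an estimated correlation; 0.0638 without control CD34+ replicate 2). B cell markers (0 up, 2 down; camera adjusted p = 0.00586, adjusted p = 0.221 with an estimated correlation) had a mean difference of -0.31, and -0.21 without control CD34+ replicate 4, and lost their call with the index (adjusted p = 0.0855). S phase genes (1 up, 1 down; camera adjusted p = 0.0288, adjusted p = 0.221 with an estimated correlation) lost their call without control CD34- replicate 3 or 4 or control CD34+ replicate 2 or 4 (adjusted p from 0.0503 to 0.0957) and with quantile normalization (0.101). Mast cell, basophil and eosinophil markers (3 up, 1 down; camera adjusted p = 0.0288, adjusted p = 0.221 with an estimated correlation) lost theirs without control CD34- replicate 3 (adjusted p = 0.0604) and with the index (adjusted p = 0.0522).

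In CD70TG mice, the fraction labelled CD34+ differed from the one labelled CD34- most in macrophage genes, which were lower in CD34+ arrays (n = 4 arrays per group). Slc40a1 was at -4.13 ± 0.15, the lipoprotein lipase gene Lpl at -4.09 ± 0.22, Axl at -3.47 ± 0.18, and Fcna at -3.38 ± 0.10. C1qb was at -3.24 ± 0.14, Ccl4 at -2.86 ± 0.15, and Mrc1 at -2.76 ± 0.12. Further falls were the organic anion transporter Slco2b1 at -2.49 ± 0.17, Emp1 at -2.46 ± 0.25 and the eosinophil granule protein Prg2 at -2.44 ± 0.56, adjusted p = 0.00907, the largest p of these. The largest rises were in Erdr1 (3.73 ± 0.52, adjusted p = 7.01e-05, the largest p among the rises), Il18r1 (3.59 ± 0.16), Ehd3 (3.41 ± 0.11), and Lpxn (2.81 ± 0.15). Rises were also large in Ackr1 (2.71 ± 0.11), Bcas1 (2.45 ± 0.17), Oosp1 (2.41 ± 0.22), the glutamate transporter Slc17a8 (2.35 ± 0.16), Esm1 (2.31 ± 0.16) and Cd96 (2.20 ± 0.16). In all, 189 genes were higher and 520 lower in CD34+ arrays, and 901 were called with the index as a covariate, all 709 shared. Of the genes called in both genotypes, 128 were higher and 279 lower in CD34+ arrays of both, where independent lists would share 7.54 and 22.5, and 1 had opposite directions (r = 0.694 across genes; the comparisons share no arrays). Cd70 (0.80 ± 0.31, adjusted p = 0.18) did not pass with all arrays, and passed without control CD34+ replicate 2 or 4, whose spread enters the shared variance (adjusted p = 0.0133 and 0.032), in a fit of the CD70TG arrays alone (adjusted p = 1.37e-05), and with the index as a covariate (0.86, adjusted p = 0.0447; adjusted p = 0.0456 with its first form).

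Monocyte and macrophage markers were lower in CD34+ arrays of CD70TG mice at 14 of 18 members and higher at 1 (the same counts adjusted over the list alone; median -1.19; camera adjusted p = 4.01e-28, adjusted p = 0.000134 with an estimated correlation). Type I interferon induced genes fell at 13 of 30 (18 down and 1 up adjusted over the list alone; camera adjusted p = 1.38e-10, adjusted p = 0.00129 with an estimated correlation). Examples are Ifit3 (-0.98 ± 0.12), Usp18 (-0.88 ± 0.12) and Oasl2 (-0.76 ± 0.11, adjusted p = 0.000167). Neutrophil granule markers fell at 14 of 18 (14 adjusted over the list alone; camera adjusted p = 4.12e-17, adjusted p = 0.0759 with an estimated correlation). Myeloid progenitor and granule genes fell at 9 of 26 (11 down and 1 up adjusted over the list alone; camera adjusted p = 8.05e-05, adjusted p = 0.171 with an estimated correlation). Immediate early and heat shock genes fell at 8 of 24 with 1 up (10 and 1 adjusted over the list alone; camera adjusted p = 0.000193, adjusted p = 0.158 with an estimated correlation). NF-kB and TNF receptor target genes were 11 up and 4 down of 28 (12 and 5 adjusted over the list alone; camera adjusted p = 0.000246, adjusted p = 0.0716 with an estimated correlation). Examples are Nfkb2 (1.84 ± 0.13), Ltb (1.82 ± 0.11) and the NF-kB inhibitor Tnfaip3 (1.19 ± 0.13, adjusted p = 5.73e-06), which rose. Dendritic cell markers were 6 up and 1 down of 14 (8 and 3 adjusted over the list alone; camera adjusted p = 0.00455, adjusted p = 0.158 with an estimated correlation). The members that rose included the class II antigen presentation genes H2-Ab1 (1.196 ± 0.154), Cd74 (1.17 ± 0.21) and H2-Eb1 (1.19 ± 0.19, adjusted p = 0.000264). Mast cell, basophil and eosinophil markers were 7 up and 3 down of 14 (8 and 3 adjusted over the list alone; camera adjusted p = 0.000246, adjusted p = 0.0577 with an estimated correlation). Their mean difference moved from 0.17 to 0.11 without CD70TG CD34+ replicate 4.

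Further lists passed in this comparison with the preset correlation alone. They were multipotent progenitor and early lymphoid genes (0 up, 3 down; camera adjusted p = 0.0221, adjusted p = 0.277 with an estimated correlation) and B cell markers (0 up, 1 down; camera adjusted p = 0.0165, adjusted p = 0.271 with an estimated correlation). G2 and M phase genes were a further list (0 up, 0 down; camera adjusted p = 0.00236, adjusted p = 0.214 with an estimated correlation). Long-term HSC genes (2 up, 5 down; camera adjusted p = 0.0209, adjusted p = 0.102 with an estimated correlation) lost their call without CD70TG CD34- replicate 1 (adjusted p = 0.0554). T and NK cell markers (2 up, 0 down; camera adjusted p = 0.0264, adjusted p = 0.162 with an estimated correlation) lost it without CD70TG CD34- replicate 1 or CD70TG CD34+ replicate 4 (0.0988 and 0.0575) and with quantile normalization (0.0663). Oxidative phosphorylation genes (0 up, 0 down; camera adjusted p = 0.0264, adjusted p = 0.214 with an estimated correlation) lost it without CD70TG CD34- replicate 1 or 3 or CD70TG CD34+ replicate 2 (adjusted p from 0.07 to 0.108). Their mean difference rose from 0.07 to 0.10 without CD70TG CD34- replicate 4. Megakaryocyte and platelet markers (2 up, 1 down; camera adjusted p = 0.0334, adjusted p = 0.342 with an estimated correlation) lost it without CD70TG CD34- replicate 2 or 3 or CD70TG CD34+ replicate 4 (0.0658 to 0.126), with the index (0.0546) and with quantile normalization (0.0531). Endothelial and stromal markers (0 up, 1 down; camera adjusted p = 0.0277, adjusted p = 0.102 with an estimated correlation) lost it without CD70TG CD34- replicate 1 or 3 or CD70TG CD34+ replicate 2 or 3 (0.0554 to 0.0619).

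The genotype difference itself differed between the fractions for 42 genes, and those with the largest such difference were mostly genes known from macrophages, higher with the transgene in CD34- but less so in CD34+ arrays (interaction, n = 4 arrays in each of the 4 groups). The difference of the CD70TG effect, CD34+ minus CD34-, was -2.81 ± 0.32 for Lpl, -2.07 ± 0.25 for Axl, -1.99 ± 0.24 for Slco2b1, -1.76 ± 0.18 for Mrc1 and -1.66 ± 0.14 for Fcna. It was -1.58 ± 0.20 for C1qb, -1.43 ± 0.21 for Slc40a1, -1.35 ± 0.21 for the lipid carrier gene Apoe, -1.25 ± 0.19 for Adgre1 and -0.89 ± 0.11 for C1qc. All 10 were at an adjusted p of 0.00286 or less. Vcam1 was at -1.84 ± 0.34, adjusted p = 0.0148, a call lost without CD70TG CD34+ replicate 4 (adjusted p = 0.0542). In the other direction, Ehd3 was at 1.05 ± 0.16, adjusted p = 0.00221. Esm1 (1.09 ± 0.22, adjusted p = 0.0351) lost its call without any 1 of 11 of the 16 arrays (adjusted p up to 0.0936). These were all of CD70TG CD34-, control CD34- replicates 1 and 2, control CD34+ replicates 3 and 4 and CD70TG CD34+ replicates 1, 2 and 4. Evc2 (0.67 ± 0.13, adjusted p = 0.0196) lost it without CD70TG CD34- replicate 1 or 3, control CD34+ replicate 1 or CD70TG CD34+ replicate 3 or 4 (up to 0.06). Mettl7b (0.47 ± 0.09, adjusted p = 0.0247) lost it without CD70TG CD34- replicate 1 or 4, control CD34- replicate 4, control CD34+ replicate 2 or 3 or CD70TG CD34+ replicate 1, 2 or 4 (up to 0.0786). Of the 42 genes, 5 were higher and 37 lower, and 57 were called with the index, 41 of them shared.

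As a list, monocyte and macrophage markers had 9 of 18 members below zero and 0 above at the threshold (15 and 1 adjusted over the list alone; median -0.82; camera adjusted p = 3.27e-26, adjusted p = 0.000192 with an estimated correlation). Megakaryocyte and platelet markers had no member called among all genes, and 10 of 15 below zero adjusted over the list alone (median -0.52; camera adjusted p = 4.36e-11, adjusted p = 0.0389 with an estimated correlation). In CD34- arrays this list was at 8.42 ± 0.10 (SD) in control and 8.52 ± 0.13 in CD70TG mice. In CD34+ arrays it was at 9.06 ± 0.14 and 8.66 ± 0.03, so the fall with the transgene was in CD34+ cells. Myeloid progenitor and granule genes had 2 of 26 members below zero (5 down and 2 up adjusted over the list alone; camera adjusted p = 0.0364, adjusted p = 0.811 with an estimated correlation). That call was lost without control CD34- replicate 2 or 3, CD70TG CD34- replicate 2 or 4, control CD34+ replicate 1 or CD70TG CD34+ replicate 4 (adjusted p from 0.0571 to 0.544, with a mean difference of -0.11 in place of -0.20 at the weakest) and with equal array medians (0.0736). For long-term HSC genes (0.0813), G2 and M phase genes (0.934) and S phase genes (0.819) the test of a difference between the fractions did not pass (camera adjusted p), which does not show that the effects were equal.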

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

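The tests of the probe discordance index, of the HSC level and of T and NK cell markers were chosen after the results were seen, and the further macrophage list was fixed before its values were seen. Over 115 named genes in 4 groups, 22 of 460 sets of 4 arrays, and over lists and the index 6 of 104, held 1 array farther from the others than Dixon's test allows at 95%, and chance gives about 1 in 20. Control CD34- replicate 3 was high for Nono (10.114), Hsp90aa1 (9.741) and Nudt3 (7.72), genes that lost their calls with the index. Flt3 was low in CD70TG CD34- replicate 2 (6.731 against 8.858 to 9.026), an array with a low index. Cd27 was low in control CD34- replicate 2 (12.54) and control CD34+ replicate 4 (12.204), and the latter array was also low for Cd79b (9.315) and dendritic cell markers (8.44) and high for Neil3 (7.612). CD70TG CD34+ replicate 1 was low for Tgm2 (9.38) and Art4 (7.658) and high for Bdh2 (9.116) and Sphk1 (8.209). CD70TG CD34+ replicate 4 was low for Hdc (10.099) and Apoe (7.295) and high for Treml1 (8.052). CD70TG CD34+ replicate 2 was high for Ackr1 (9.236) and ribosome biogenesis genes (10.62), and CD70TG CD34+ replicate 3 was low for S phase genes (10.76) and high for G2 and M phase genes (10.33). Control CD34- replicate 4 was low for Unc45b (10.289) and high for Rrm2 (8.967), and replicate 1 was high for Oosp1 (7.614). CD70TG CD34- replicate 1 was low for Fpr2 (9.259), and replicate 4 was low for Slco2b1 (9.86) and high for oxidative phosphorylation genes (11.76). In control CD34+ arrays, replicate 2 was high for Prg2 (8.171) and replicate 1 for interferon gamma induced genes (9.68).

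The genotype effect differed between the fractions, by the interaction test, for Lpl (-2.81), Axl (-2.07), Slco2b1 (-1.99), Vcam1 (-1.84), Mrc1 (-1.76), Fcna (-1.66), C1qb (-1.58), Slc40a1 (-1.43), Apoe (-1.35), Adgre1 (-1.25) and C1qc (-0.89), and upward for Esm1 (1.09), Ehd3 (1.05), Evc2 (0.67) and Mettl7b (0.47). The calls of Vcam1, Esm1, Evc2 and Mettl7b each depend on single arrays (adjusted p up to 0.0542, 0.0936, 0.06 and 0.0786 when 1 is left out), none of the 4 passed against a minimum fold of 1.2, and Esm1 and Evc2 did not with quantile normalization (0.0647 and 0.0853). By list medians it differed for monocyte and macrophage markers (-0.82), megakaryocyte and platelet markers (-0.52) and myeloid progenitor and granule genes (-0.16), the last not with an estimated correlation (adjusted p = 0.811).

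HSC genes fell and cell cycle, granule, respiratory and ribosome biogenesis genes rose in CD70TG arrays. The probe discordance index was also higher there on average, and in CD34- arrays its values did not overlap between the genotypes. Its exact permutation test (adjusted p = 0.114 in both fractions) had little room to pass, since 4 against 4 arrays give at least 0.0286 before adjustment. In CD34- cells the calls of the respiratory and ribosome biogenesis lists were lost with an estimated correlation (camera adjusted p = 0.0553 and 0.136). So was that of ribosome biogenesis in CD34+ cells (0.0623) and on the average (0.0711). The index as a linear covariate did not remove 4 lists, which stayed under 0.05 in both fractions by camera with an estimated correlation. The largest p was 3.24e-06 for HSC, 0.000117 for G2 and M phase, 0.000664 for S phase and 0.00403 for granule genes. This fit cannot exclude the axis behind the index, since the index comes from these same arrays and is not balanced over the genotypes. In CD34- cells the mean difference of oxidative phosphorylation genes went from 0.41 ± 0.04 to 0.31 ± 0.06 (SE), and that of ribosome biogenesis genes from 0.25 ± 0.04 to 0.27 ± 0.06. Cells of the kind sorted as CD34+ from control mice, had they entered the CD34- gate of CD70TG mice, could not have lowered the HSC list below their own level. The list was at 8.37 ± 0.02 (SD) in CD70TG CD34- and 8.98 ± 0.06 in control CD34+ arrays, a difference of -0.61 (exact permutation p = 0.0286, the smallest possible). Control CD34- arrays were at 9.01 ± 0.06, close to control CD34+ arrays. The comparison therefore restates the genotype difference and is not a separate test of the gate. More committed progenitors within the gates of CD70TG mice, and a change of the HSC themselves with the transgene, both stay open as hypotheses, since no value here separates them.

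Macrophage genes were higher in CD34- than in CD34+ arrays, more so in CD70TG mice, and macrophages or their RNA in the CD34- sort are a candidate, although the lineage-negative, c-Kit+, Sca-1+ gate should remove them. A further list of 19 measured macrophage genes, none in the fixed lists and 8 of them at a level of 8 or more in control CD34+ arrays, was lower in CD34+ arrays of CD70TG mice at 11 members and higher at 0 (camera p = 1.64e-06 with an estimated correlation). Of its members, Ctsb differed by -1.03 and Lgals3 by -1.62, while Psap (-0.44, adjusted p = 0.151) and Ctsd (-0.10, adjusted p = 0.755) moved the same way without passing. If all other cell types took a larger share of the CD34- sort alike, their markers would all be lower in CD34+ arrays. The list levels moved apart instead (± SE). They were at -1.43 ± 0.06 for macrophages, -1.02 ± 0.19 for neutrophil granules, -0.28 ± 0.12 for B cells, -0.24 ± 0.16 for erythroid and -0.19 ± 0.07 for endothelial markers. T and NK cell markers were at 0.16 ± 0.04 and dendritic cell markers at 0.24 ± 0.09. Megakaryocyte and platelet markers were at 0.15 and mast cell, basophil and eosinophil markers at 0.17. The T and NK cell list lay not far above background (7.17 in CD70TG CD34- and 7.33 in CD70TG CD34+ arrays), so it reads the share of those cells poorly. A larger share of single types would move their own markers alone, which these values cannot exclude, so that neutrophils beside macrophages stay open. With the probe discordance index as a linear covariate the interaction of the macrophage list stayed at p = 1.3e-05 (camera test, estimated correlation). The index entered in this way did not account for the interaction, and expression of these genes by the stem cells themselves was not tested.

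The genes that lose their genotype call with the index as a covariate are a pattern of their own, given here as values. In CD34- cells Nono went from 3.14 to 0.16, Hsp90aa1 from 2.92 to 0.44, Hspa5 from 2.40 to 0.42, Flt3 from 1.94 to 0.02 and Cd48 from 1.68 to 0.43, and the number of called genes from 3287 to 760. The SE of these 5 genes was smaller in that fit (0.57 to 0.249 for Nono, 0.27 to 0.225 for Cd48), so their calls were lost because the estimates fell, although a p above the threshold does not show that no difference is left. It was also smaller for Nudt3, Uqcrb and Atp5a1. For Ndufa4, Mzb1 and Cd79b the SE was larger with the index (0.178, 0.268 and 0.156). Lost precision can therefore also enter the drop in the number of called genes. Whether the axis is technical or follows the state of the cells was not settled, since the labels name no batch and the index is not balanced over the genotypes.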

How the results depend on the processing

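Tests chosen after the data were seen are those with quantile normalization, equal array medians, without both arrays that stood apart, and with either form of the probe discordance index. The others were planned, but the stricter filter was planned on detection p-values and redefined after the files were seen. Not run were no background correction, normexp with an offset of 50, neqc with scaled medians and the slide as a block, which needed the table not used here; the deposited values, planned as an alternative, became the basis of all results. Between genotypes in CD34- cells, in CD34+ cells and on the average, and between fractions in control and CD70TG mice and for the interaction, a minimum fold of 1.2 left 1081, 545, 1315, 211, 286 and 19 genes, since it is a stricter hypothesis. With the index, the genotype counts were 760, 1113 and 1185, and with its first form 688, 1065 and 1093. Array weights gave 3318 in CD34+ cells and 1421 between fractions of CD70TG mice; the cause was not tested. The control arrays alone gave 482 between fractions, with fewer arrays to estimate the spread. Leaving out 1 array gave 2518 to 3547, 1457 to 2738, 4109 to 4813, 622 to 1172, 535 to 742 and 29 to 58 genes, in that order. Without both arrays that stood apart the counts were 3706, 3025, 5009, 729, 659 and 40. The labels do not say whether equal replicate numbers pair the arrays. Of the same-numbered pairs, 10 of 24 had deviations correlated above 0.1 (-0.33 to 0.65), and 5 of 16 arrays matched their own number best. Between the fractions of CD70TG mice the pairs were at 0.443, 0.653, -0.030 and 0.158, and between those of control mice at 0.064, 0.109, -0.307 and -0.079. Pairing is therefore not excluded. Fits with the replicate number joined control and CD70TG arrays of the same number, which come from different mice. Separate blocks within each genotype, which would pair the fractions of the same mice, were not fitted. The counts of the fits with the replicate number therefore do not show how such pairing would change the p-values. The replicate block gave 3388, 2399, 4655, 1074, 732 and 46 genes, changed no list call, and among named genes changed only Flt3 in CD34+ cells (adjusted p = 0.018). As a random effect, run for genes and not for lists, it changed among named genes only Cd27 in CD34- cells (adjusted p = 0.049), which passed also with array weights (0.00682), the stricter filter (0.0441) and quantile normalization (0.00752). Signs turned for Nudt3 in CD34- cells (-0.35 with the index, -0.49 with its first form), Flt3 (-0.053 in CD34- cells with the first form, -0.16 and -0.20 in CD34+ cells with both), Cd34 (0.20 and 0.23 in CD34- cells, 0.18 and 0.19 in CD34+ cells) and Cd70 in CD34- cells (0.70 and 0.72), none past the threshold. Cd34 in CD34+ cells also turned with quantile normalization (0.0145), and ranged from -0.116 to 0.0573 over single arrays left out, turning without control CD34+ replicate 1 or 3 or CD70TG CD34+ replicate 1. Of 179 values of named genes, 157 kept direction and side of the threshold with the index, 156 with its first form, 175 with quantile normalization, 179 with equal medians, 171 against the minimum fold and 2819 of 2864 over single arrays left out. Of 69 called lists, 28 held with an estimated correlation, 64 with the index, 66 with quantile normalization, 68 with equal medians and 64 without both arrays that stood apart. Signal limits the reach: values near background are compressed, and between fractions of control mice 60% of genes changed by 0.5 log2 were recovered in simulated data with independent genes.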

Other observations

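The test of imprinted genes was fixed before its values were seen and the splits of the samples were planned, whereas the idea of imprinted genes came from the results. Cdkn1c, Ndn, Snrpn and Grb10, all imprinted genes, were among the largest falls with the transgene. The hypothesis that imprinted genes fall as a group was tested on 13 other measured imprinted genes, averaged over both fractions. Of these, 3 fell, namely Slc22a18 (-0.76 ± 0.11), Impact (-0.50 ± 0.08) and Mkrn3 (-0.38 ± 0.09), and Peg12, near background, rose (0.19 ± 0.07). The list did not pass (median -0.02, camera p = 0.358 with an estimated correlation), and with the probe discordance index as a covariate the p was 0.0222, a fit chosen after the fact. By the bound fixed beforehand, a p of 0.05 or more, the hypothesis would count as rejected. It is left undecided here, a change made after the result was seen, because a p above the threshold does not show that the genes did not fall.

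Cd70, whose product is made in excess in the transgenic mice by design, was higher and more spread in control CD34+ arrays, at 8.29 ± 1.05 (mean ± SD), against 6.80 ± 0.10 in CD70TG CD34+ arrays. It was higher in CD34+ than in CD34- control arrays by 2.15 ± 0.31.

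Other splits of the arrays into groups of the same size were counted for each comparison. In all 6 no other split called as many genes as the real one (1 of the splits in each), and with 35 splits this is the strongest result that the arrays allow. Between genotypes in CD34- cells the real split called 3287 genes and the highest of the other 34 of 35 splits 663, and in CD34+ cells 2153 and 236. Between fractions the counts were 984 and 112 of 35 splits in control mice, and 709 and 3 of 35 in CD70TG mice. For the average the real split called 4608 genes and the highest of the others among 100 drawn 61. For the interaction the real data called 42 genes and the highest of the shuffles 0. In the highest other split between genotypes, CD70TG replicate 2 changed places with control replicate 3 in CD34- cells and with control replicate 4 in CD34+ cells. These are the control arrays with the highest and the CD70TG arrays with the lowest probe discordance index of their groups. In CD34+ cells the exchange follows the order of the index (0.729 in control replicate 4, 0.319 in CD70TG replicate 2). In CD34- cells it does not, since control replicate 3 (-0.519) lay below CD70TG replicate 2 (-0.304).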
